A study of Mus musculus with 40 samples.

How the data were processed

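RNA, accessible chromatin and ThPOK binding were measured in mouse T cells, with single-cell RNA from 3 tissues of 1 mouse. The series held 23 RNA libraries of sorted cells, 12 ATAC libraries (an assay in which a transposase inserts adapters into open chromatin), 1 ThPOK chromatin immunoprecipitation (ChIP) with 1 input, and 3 single-cell libraries. WT denotes the reporter genotype iFoxp3TomThPOKGFP, in which cells that had Foxp3 when marked carry tdTomato and ThPOK reports as GFP, and FF the genotype with ThPOK deleted in those cells. Groups, mice, mouse pools and sequencing batches were taken per the labels.

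For bulk RNA, the deposited tables gave expected counts (estimated reads per transcript) and TPM (abundance scaled for transcript length) for 141767 transcripts, in the column format of kallisto. The submitters' processing notes name kallisto 0.46.0 and sleuth 0.30.0. The expected counts were rounded and used here, and the TPM served only for the alternative with length-scaled counts. The tables name transcripts and come with no map to genes, and no such map was at hand, so each transcript was tested by itself. Fixed gene lists were therefore not tested in bulk RNA, nor was the level of Zbtb7b checked there, and the planned joins of RNA changes with ATAC gains and with ThPOK-bound genes were not run.

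Each contrast was fitted with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM scaling, robust quasi-likelihood fit and test) in R 4.3.3, and a transcript was called at a Benjamini-Hochberg adjusted p under 0.05. One model held the 13 libraries of the 5 WT groups with sequencing batch as a term, and another held the 18 libraries of the 3 populations present in both genotypes without it, because all but 1 FF library came from a batch with no WT library. Called lists were tested in other contrasts with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. A score per library was the mean log2 CPM (prior count 2) of the transcripts called higher minus that of those called lower, compared between groups by exact 2-sided permutation of libraries. It was computed on the calls between CD4-IEL and iTreg-IEL and on those between CD4-IEL and iTreg-MLN, the latter from a fit of these 6 libraries alone without batch. Differences of shifts between populations were compared by permuting genotype over mice, and the score was added after the data were seen. Named genes followed a rule fixed beforehand: the 2 largest called changes per direction and contrast, the 16 loci, the 5 ThPOK regions of highest signal within 10 kb of a gene, and the 5 largest single-cell ratios per pair of tissues, with the genes of fixed lists. From the called transcripts, those called in several contrasts were taken after their values were seen. Among genes of lists, the members printed were chosen after their values were seen. Folds against a group with no count were set against 3 counts over the group.

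For ATAC, the deposited lists held pooled regions of both libraries of a group on GRCm38/mm10, 1 list per group. Per the file headers and format, the deposited columns gave fold enrichment (a ratio), -log10 p and -log10 q values and the summit offset (other). The submitters' processing notes name Bowtie2, SAMtools, MACS2 and HOMER, and their versions and the reads behind each list are not given in the sources used here. Summits of 1 interval were merged to 1 region. A region was gained or lost when no region of the other list overlapped it by at least 1 bp, and it was assigned to a gene when its strongest summit lay in the gene or within 10 kb. In totals of a list, a region near several of its genes counts once for each. For each fixed list of genes (16 lists), gained minus lost regions were set against 10000 random lists of genes matched for their number of regions, as a description and not a test, since no list had a replicate. Matching did not cover how near the genes of a list lie to each other, and neighbouring genes share regions.

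For ThPOK, 1 immunoprecipitation gave a deposited list with a signal score whose unit is not stated by the authors, used as the main list, and a deposited list with fold enrichment (ratio) and -log10 p, used as the alternative. No replicate existed, so shares carry exact binomial intervals (Clopper-Pearson, 95%) that cover counting error only.

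For single cells, the deposited matrices held UMI counts, with version 3.0.2 in the file headers and Cell Ranger 3.0.2 named in the submitters' processing notes, and with tdTomato, eGFP and Foxp3ERt2 as added features, and the feature and barcode tables (other) gave names alone. Cells with at least 500 genes and under 10% mitochondrial UMIs were kept. Clusters came from scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8). A cluster was named "X-like" only when at least 3 markers of a fixed class were at least 2-fold higher in it and in at least 10% of its cells, and otherwise stayed unnamed. Named clusters also had more markers of their class than of other classes among their 10 top genes. Clusters with at least 3 markers that stayed unnamed did not. The rule was tightened after the data were seen. Scrublet marked 0.137% to 0.461% of cells, too few to have worked at these cell numbers, so doublets were kept. Levels are summed UMIs scaled to library totals (CPM) with exact Poisson intervals at 95%, and shares of cells carry exact binomial intervals. Both cover counting error only, and no test between tissues was made, because each tissue was 1 library of 1 mouse. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs. Genes outside the fixed lists were named when they had at least 50 UMIs and a ratio of at least 4.

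The models were tested on simulated data. In the WT fit, changes of 1, 2, 4 and 8 on the log2 scale planted in 50 transcripts each were called in 2%, 10%, 62% and 86% of cases between CD4-IEL and iTreg-IEL, with 4 unchanged transcripts called. In the genotype fit the same changes were called in 0%, 2%, 36% and 72%, with 1 unchanged transcript called. Changes were planted in better expressed transcripts alone, so these shares do not hold for transcripts at lower levels. In simulated single-cell libraries, intervals lay apart for 84% of genes changed 1.5-fold and for 3.29% of unchanged genes. Alternatives covered the tool (DESeq2 1.42.0), scaling, the low-count filter, length-scaled counts, batch, mouse as a block, the male FF mouse, each library left out, region overlap, strength and list size, gene distance, cell filter, cluster resolution and doublets. The design, its contrasts and these alternatives were fixed before the data were examined, and later additions are named as such.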

Results

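The study compared sorted CD4 T cells with regard to the intraepithelial lymphocyte (IEL) program that some of them take on in the gut epithelium. The labels give no time course, so differences between populations are not shown to be changes within 1 lineage. Regions gained or lost are differences between lists. RNA was measured in CD4-IEL (n = 3), preIEL (n = 2), exTreg-IEL (n = 2, cells marked by earlier Foxp3 expression that have lost it), iTreg-IEL (n = 3) and iTreg of the mesenteric lymph node (iTreg-MLN, n = 3) of WT mice, and in exTreg-IEL (n = 4), iTreg-IEL (n = 3) and iTreg-MLN (n = 3) of FF mice, in which ThPOK, the transcription factor encoded by Zbtb7b that keeps CD4 T cells in the helper lineage, was deleted. Each RNA library came from 300 to 800 sorted cells. Totals per library lay between 15824442 and 29068497 estimated counts in CD4-IEL, 20331480 and 21046585 in preIEL, 22174593 and 23305660 in exTreg-IEL, 19685350 and 26314139 in iTreg-IEL and 19292887 and 22214542 in iTreg-MLN of WT mice. In FF mice they lay between 21460085 and 30347985 in exTreg-IEL, 14199966 and 29114701 in iTreg-IEL and 24964509 and 29196311 in iTreg-MLN. The exTreg-IEL FF replicates 2 and 3 held 34813 and 39623 detected transcripts, against at least 45683 in each other library. Accessible chromatin was listed for CD4-IEL, preIEL, exTreg-IEL and iTreg-IEL of WT mice and for exTreg-IEL and iTreg-IEL of FF mice, with 1 pooled list of 2 libraries per group. Single-cell libraries of 1 male WT mouse held 1519 cells of the mesenteric lymph node (MLN), 2499 of the lamina propria (LPL) and 2921 of the epithelium (IEL), with median depths of 2012, 2202 and 2332 UMIs.

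The ATAC lists addressed how chromatin differs between iTreg-IEL and CD4-IEL in WT mice. Of 212 regions near genes of the Treg list in iTreg-IEL (209 with a region near several such genes counted once), 62 were lost in CD4-IEL, and 7 were gained, below all 10000 matched lists (median of these, 6 more gained than lost). Ikzf2, which encodes Helios, a factor of stable regulatory T cells, had 44 regions in iTreg-IEL, 45 in preIEL, 44 in exTreg-IEL and 17 in CD4-IEL within 10 kb (gene at chromosome 1, 69531207 to 69687351, GRCm38/mm10). Il2ra, the high-affinity IL-2 receptor chain (chromosome 2, 11642792 to 11693194), had 12, 14, 10 and 8. At Foxp3, the lineage factor of regulatory T cells (chromosome X, 7579676 to 7595243), a region inside the gene at 7583694 to 7584436 was listed in iTreg-IEL, preIEL, exTreg-IEL and both FF groups and not in CD4-IEL.

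Genes of the CD8 lineage and of natural killer receptors had more regions in CD4-IEL. The CD8 lineage list had 25 gained and 5 lost regions against iTreg-IEL (percentile 98.5 of matched lists), with 7 gained at Ikzf3, 5 at Zeb2 and 2 each at Cd8a, Cd8b1 and Runx3. The natural killer receptor list had 26 gained and 7 lost (percentile 99.5), with 6 gained at Cd226, 4 at Klrd1 and 3 each at Klre1 and Klrb1c. The gut residency list had 29 gained and 9 lost (percentile 97.7, and 91.5 with equal list sizes), with 5 gained and 2 lost at Itgae, the integrin chain that binds epithelial cadherin. The cytotoxic list had 10 gained and 3 lost (percentile 92.1), and the CD4 helper list 14 gained and 27 lost (percentile 1.23, and 3.25 within 50 kb), 13 of the lost at Tox. These totals count a region once for each gene of the list that it lies near, as in the matched lists, and with each region counted once the natural killer receptor list had 22 gained and 7 lost. Matched lists were not drawn as neighbouring genes, so the percentile of this list may be too extreme. No percentile is given with each region counted once. Cd8a (chromosome 6, 71373427 to 71379171) had 3 regions in iTreg-IEL, 1 in preIEL, 8 in exTreg-IEL and 5 in CD4-IEL, as the map of both loci shows. Of the 16 loci fixed for inspection, 9 had more regions in CD4-IEL than in iTreg-IEL, 3 fewer and 4 as many.

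**Figure D1:**
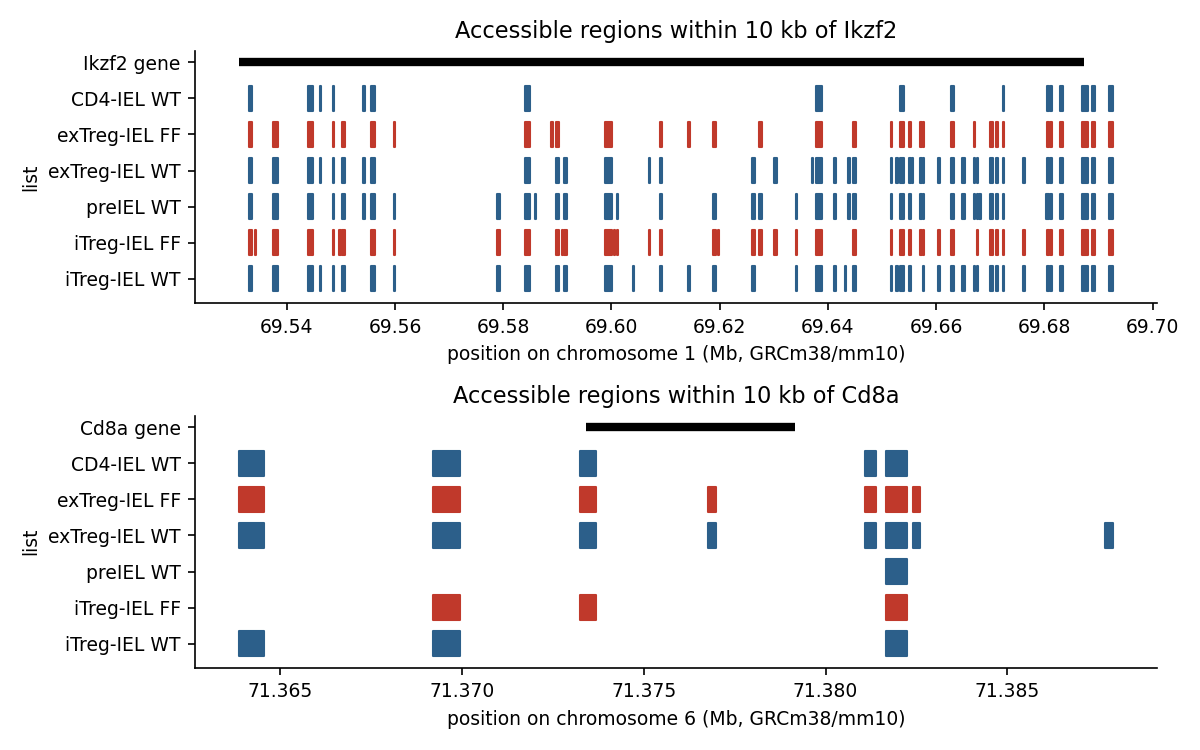
Accessible regions (boxes, to scale) within 10 kb of Ikzf2 and Cd8a in each pooled list, WT in blue and FF in red, with the gene as a black bar and position in Mb on GRCm38/mm10. CD4-IEL had 17 regions at Ikzf2 against 44 in exTreg-IEL WT, and preIEL had 1 region at Cd8a.

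The preIEL and exTreg-IEL groups differed in what they shared with CD4-IEL. The preIEL list held 26.4% (95% interval 25.5 to 27.4) of the 7853 regions found in CD4-IEL and not iTreg-IEL, and 67.6% (66.5 to 68.7) of the 7001 found in iTreg-IEL and not CD4-IEL. In exTreg-IEL these shares were 43.4% (42.3 to 44.5) and 43.8% (42.6 to 44.9), as the plot of these shares shows. The lymphoid homing list, which includes genes of naive and recirculating cells, had 65 gained and 10 lost regions in preIEL against iTreg-IEL (percentile 99.985), and 16 gained and 83 lost in CD4-IEL against preIEL (percentile 0.445, and 3.32 with equal list sizes). The CD8 lineage list had 12 gained and 18 lost in preIEL against iTreg-IEL (percentile 1.82, and 3.88 with reciprocal overlap), 36 gained and 10 lost in CD4-IEL against preIEL (percentile 99.8), and 23 gained and 5 lost in exTreg-IEL against iTreg-IEL (percentile 99.8, and 91.2 with equal list sizes). The Treg list had 14 gained and 30 lost in exTreg-IEL against iTreg-IEL (percentile 0.325) and 8 gained and 44 lost in CD4-IEL against exTreg-IEL (percentile 0.03). Regions near epithelial marker genes also differed, with 11 gained and 1 lost in exTreg-IEL against iTreg-IEL (percentile 99.9) and 1 gained and 17 lost in CD4-IEL against exTreg-IEL, below all matched lists. With equal list sizes these were 2 and 1 (percentile 76.2) and 1 and 2 (percentile 25.2).

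**Figure D2:**
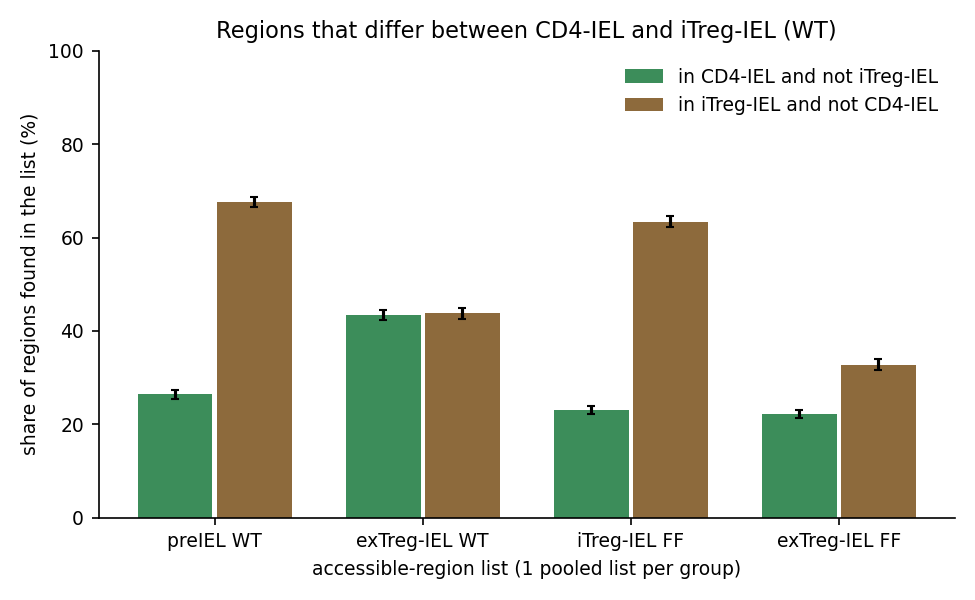
Share (%) of regions listed in only 1 of CD4-IEL and iTreg-IEL (WT) that were found in each other list (green, listed in CD4-IEL; brown, listed in iTreg-IEL), with exact 95% binomial intervals for counting error. The preIEL list held 26.4% of the regions of CD4-IEL and 67.6% of those of iTreg-IEL.

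In numbers, preIEL against iTreg-IEL had 11053 regions gained and 5863 lost, CD4-IEL against preIEL 9365 and 13674, CD4-IEL against iTreg-IEL 7853 and 7001, exTreg-IEL against iTreg-IEL 6906 and 6276, and CD4-IEL against exTreg-IEL 6806 and 6583. With equal list sizes the preIEL counts were 6063 and 6102, and the preIEL share of regions of CD4-IEL was 17.4%. No group had a replicate list, so no difference between groups was tested.

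RNA of the WT populations addressed the same comparisons. ENSMUST00000205054.1 was at 663 ± 241 CPM (SD, n = 3) in CD4-IEL and 521 ± 107 (n = 2) in exTreg-IEL, and had no count in preIEL, iTreg-IEL or iTreg-MLN. It was at least 14952-fold higher in CD4-IEL than iTreg-IEL and at least 9138-fold higher than in preIEL (edgeR adjusted p = 0.0051 and 0.0399). ENSMUST00000025192.7 was at 44.7 ± 2.85 CPM (n = 3) in iTreg-MLN, 23.1 ± 6.65 (n = 3) in iTreg-IEL and 11.4 ± 3.12 (n = 2) in preIEL, and had no count in CD4-IEL or exTreg-IEL. It was at least 235-fold lower in CD4-IEL than preIEL (edgeR adjusted p = 0.0238) and at least 351-fold lower in exTreg-IEL than iTreg-IEL (edgeR adjusted p = 0.0251). Both transcripts thus passed the test in CD4-IEL against preIEL and in exTreg-IEL against iTreg-IEL. With mouse as a block in place of batch, edgeR called 0 transcripts in the latter contrast and 0 higher in the former. With that block ENSMUST00000205054.1 thus kept neither call. Whether its gene was a marker of the sort is not known without a map to genes.

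Of 55009 transcripts tested, edgeR called 37 higher and 79 lower in CD4-IEL than iTreg-IEL, with a median size of 3.20 on the log2 scale. It called 45 higher and 3 lower in iTreg-IEL than iTreg-MLN, 3 higher and 7 lower in CD4-IEL than preIEL, 8 higher and 7 lower in exTreg-IEL than iTreg-IEL, and 1 higher and 5 lower in CD4-IEL than exTreg-IEL. Between preIEL and iTreg-IEL edgeR called 0. An unadjusted p under 0.05 was found for 2386 (4.34%), no more than the share of 0.05 that chance gives. DESeq2 called 1554, but it also called 900 to 1310 in mixed splits of the CD4-IEL and iTreg-IEL libraries. Such splits keep part of the real difference, so not all calls there need be false, and no split of preIEL libraries was fitted. The counts of DESeq2 were thus not read as numbers of real changes. With mouse as a block in place of batch, edgeR called 33 in all between CD4-IEL and iTreg-IEL, 21 between iTreg-IEL and iTreg-MLN and 4 between CD4-IEL and preIEL. It called 0 for exTreg-IEL against iTreg-IEL or CD4-IEL against exTreg-IEL, where DESeq2 without the block called 2177 and 1720. Without the block, 3119 (5.67%) and 2406 (4.37%) had an unadjusted p under 0.05 in edgeR, near the share that chance gives. Leaving out any 1 of the 6 libraries compared gave 45 to 55 calls between CD4-IEL and iTreg-IEL. Without iTreg-IEL replicate 1, 2 or 3, exTreg-IEL against iTreg-IEL had 1, 0 and 0 calls, and without exTreg-IEL replicate 1 it had 23. Between CD4-IEL and preIEL there were 1, 1 and 2 calls without CD4-IEL replicate 1, 2 or 3, and 3 without preIEL replicate 2. CD4-IEL against exTreg-IEL had 0, 0 and 1 without those CD4-IEL replicates and 20 without exTreg-IEL replicate 1. Without iTreg-IEL replicate 1 or 3, iTreg-IEL against iTreg-MLN had 24 and 25.

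The place of each population between iTreg-MLN and CD4-IEL was scored on 112 transcripts called higher and 126 called lower in CD4-IEL than iTreg-MLN, a list that iTreg-IEL, preIEL and exTreg-IEL had no part in choosing. From 0% for iTreg-MLN to 100% for CD4-IEL, iTreg-IEL of WT mice lay at 37.0% ± 2.86 (SD, n = 3), preIEL at 69.6% ± 0.480 (n = 2) and exTreg-IEL at 86.6% ± 0.825 (n = 2). Both ends are the libraries that chose the list, which can set the ends apart. Part of the distance of other libraries from either end may thus come from this choice. The score of preIEL was 3.79 above that of iTreg-IEL on the log2 scale, with no overlap of libraries and an exact permutation p of 0.1, the smallest that 2 against 3 libraries allow. FF iTreg-IEL lay at 64.8% ± 6.78 (n = 3), FF exTreg-IEL at 82.9% ± 3.67 (n = 4) and FF iTreg-MLN at 8.69% ± 2.29 (n = 3).

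**Figure D3:**
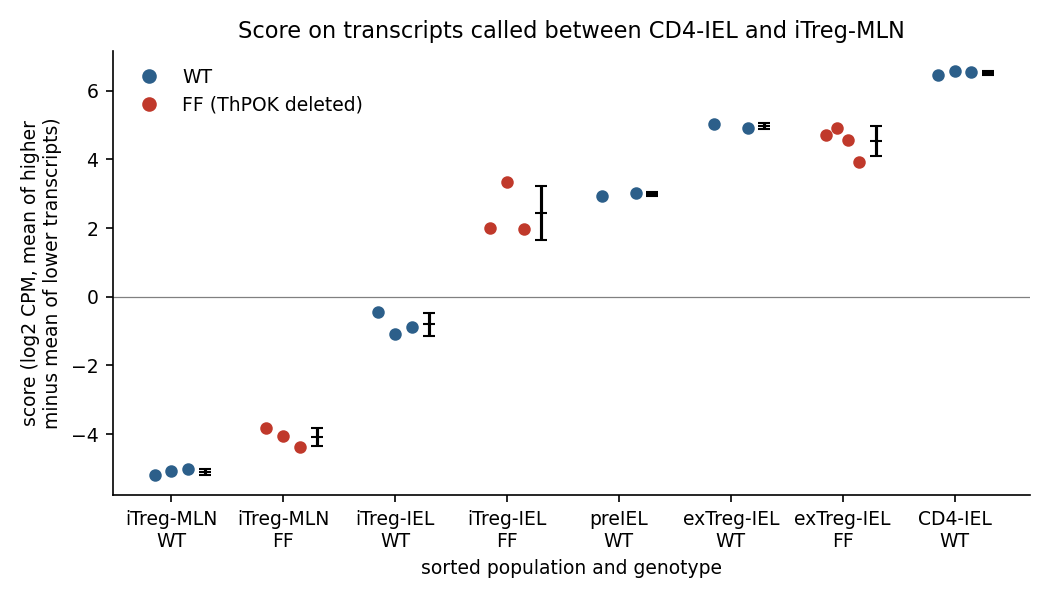
Score of each RNA library (points, WT blue and FF red; black, mean ± SD) on transcripts called between CD4-IEL and iTreg-MLN of WT mice, in log2 CPM. The 3 FF iTreg-IEL libraries lay between 1.96 and 3.35 and the 3 WT ones between -1.08 and -0.44.

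Deletion of ThPOK addressed whether this factor holds Treg cells away from the IEL program. The score of iTreg-IEL was 3.24 higher in FF than WT mice, and all 3 FF libraries lay above all 3 WT libraries (exact permutation p = 0.1, the smallest possible). In iTreg-MLN it was 1.01 higher (exact p = 0.1, the smallest possible), and in exTreg-IEL the difference was -0.43 (exact p = 0.267). The shift in iTreg-IEL exceeded that in exTreg-IEL by 3.67 (exact p = 0.0286, the smallest possible, adjusted 0.0571) and that in iTreg-MLN by 2.23 (exact p = 0.0857, adjusted 0.0857), with genotype permuted over mice, since 4 and 5 mice gave libraries of both populations. The list was called with the WT iTreg-MLN libraries, which also enter both comparisons that involve iTreg-MLN. Genotype followed sequencing batch in iTreg-IEL and iTreg-MLN, whose FF libraries all came from a batch without WT libraries, so genotype and batch cannot be told apart there.

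ENSMUST00000205054.1, at 0 in WT iTreg-IEL, was at 11.4 ± 3.77 CPM (n = 3) in FF iTreg-IEL, at least 256-fold higher (edgeR adjusted p = 1.8e-04) and 1.64% of its level in FF exTreg-IEL, and had no count in FF iTreg-MLN. ENSMUST00000163304.2 was at 25.5 ± 5.83 CPM (n = 4) in exTreg-IEL, 26.3 ± 2.72 (n = 3) in iTreg-IEL and 38.3 ± 3.45 (n = 3) in iTreg-MLN of FF mice and at 0.15 or below in every WT group. ENSMUST00000074680.7 was at 395 ± 93.4 CPM (n = 2), 475 ± 29.1 (n = 3) and 745 ± 93.0 (n = 3) in these populations of WT mice, which was 358-fold, 591-fold and 309-fold above FF. Both passed the edgeR test in each population, as the plot of transcript levels shows. Every FF library differed from every WT library, in iTreg-MLN too, and whether this came from ThPOK deletion was not tested.

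**Figure D4:**
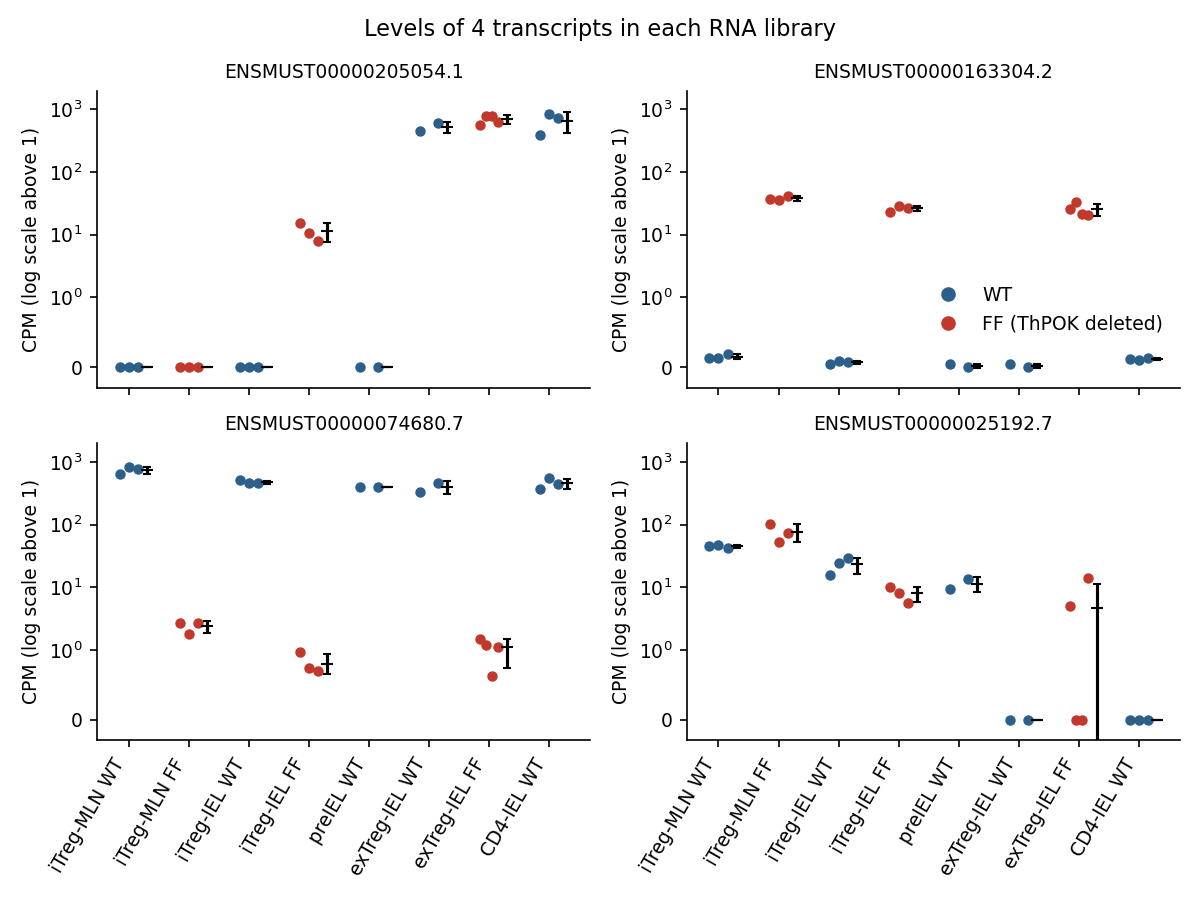
Levels (CPM, log scale above 1) of 4 transcripts in each RNA library (points, WT blue and FF red; black, mean ± SD). ENSMUST00000205054.1 was at 663 CPM in CD4-IEL and 11.4 in FF iTreg-IEL, and ENSMUST00000074680.7 was at 0.80 to 2.41 in FF groups.

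Of 59857 transcripts, edgeR called 3 higher and 2 lower in FF than WT exTreg-IEL, 3 higher and 2 lower in iTreg-IEL, and 5 higher and 1 lower in iTreg-MLN. In iTreg-MLN, 2 were called with sequencing batch as a term, 14 without the male FF mouse and 12 without the low-count filter. Each pair of populations shared 2 of those higher and 1 of those lower (Fisher's exact p at most 6.7e-05). This test assumes independent comparisons, but libraries of the same mice and batches entered them. Its p thus does not measure agreement between populations. The difference in genotype effect between exTreg-IEL and iTreg-IEL was called for 3 transcripts, and that between iTreg-IEL and iTreg-MLN for 0 by edgeR. For the latter, 3291 (5.50%) had an unadjusted p under 0.05, near the share that chance gives, and DESeq2 called 1061. In FF mice, 1 transcript was higher and 1 lower in exTreg-IEL than iTreg-IEL, and 4, 5 and 6 were called without exTreg-IEL replicate 2, exTreg-IEL replicate 4 or iTreg-IEL replicate 1. Without FF exTreg-IEL replicate 1 or 4, 8 were called between genotypes in exTreg-IEL. The first difference of effects had 6 calls without FF exTreg-IEL replicate 4, and 1 without WT exTreg-IEL replicate 2 or any 1 WT iTreg-IEL replicate. With limma voom in place of edgeR, 124, 87 and 96 transcripts were called in exTreg-IEL, iTreg-IEL and iTreg-MLN, and 124, 87 and 104 with mouse as a random block as well (within-mouse correlation 0.0039), so most of this rise came with the tool. With mouse as a fixed block, edgeR called 0 between FF exTreg-IEL and FF iTreg-IEL and 0 for the first difference of effects, where 4990 and 4264 had an unadjusted p under 0.05 without the block and DESeq2 called 1332 and 1440.

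The WT calls were also tested as lists. The list of 3 transcripts higher in CD4-IEL than preIEL ranked above the other transcripts in FF against WT iTreg-IEL by camera (2 of 3 positive, median log2 change 4.59, adjusted p = 3.2e-09, and 1.1e-04 with an estimated correlation). It includes ENSMUST00000205054.1, itself called in this contrast, so the list gives no separate support. Another member, ENSMUST00000066747.13, was at 0 CPM in WT and 2.18 in FF iTreg-IEL. The list of 7 lower ones ranked below the others (0 of 7 positive, median -1.05, adjusted p = 0.0201), a call lost with an estimated correlation (adjusted p = 0.332), and with batch as a term they went the other way without a call (adjusted p = 0.927). The list of 37 higher in CD4-IEL than iTreg-IEL ranked above the others in iTreg-MLN (24 of 37 positive, median 0.02 against -0.02 over all transcripts, adjusted p = 0.0284). This was 64.9% positive, against 49.3% of all transcripts and 64.3% of those above 5 on the log2 CPM scale, and the call was lost with an estimated correlation (adjusted p = 0.567) and with batch as a term (adjusted p = 0.642). In exTreg-IEL no list passed the test.

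In chromatin, FF iTreg-IEL against WT had 7106 regions gained and 6185 lost, and FF exTreg-IEL against WT had 3552 gained and 12341 lost, or 5225 and 7174 with equal list sizes. The Treg list had 36 gained and 15 lost regions in FF iTreg-IEL (percentile 93.4, and 99.5 with equal list sizes), and the natural killer receptor list 8 gained and 17 lost (percentile 2.5, and 1.64 with reciprocal overlap). The FF iTreg-IEL list held 23.1% of the regions of CD4-IEL absent from WT iTreg-IEL, and 63.4% of those lost. In FF exTreg-IEL these shares were 22.2% and 32.8%, and 36.1% and 51.7% with equal list sizes, so they depend on the length of the lists. In FF mice, exTreg-IEL against iTreg-IEL had 6 gained and 61 lost regions near the Treg list (percentile 0.195) and 18 gained and 14 lost near the CD8 lineage list (percentile 99.9, where the median of matched lists was 15 more lost than gained). Cd8a had 7 regions in FF exTreg-IEL and 3 in FF iTreg-IEL, and Ikzf2 had 36 and 47. Epithelial markers had 1 gained and 8 lost regions in FF iTreg-IEL against WT (percentile 0.15) and 0 gained and 21 lost in FF exTreg-IEL, below all matched lists, or 0 and 2 (percentile 24.4) and 0 and 5 (percentile 3.12) with equal list sizes. WT and FF lists came from different mouse pools, and only 1 batch held libraries of both. Sex also differed with genotype, since per the labels the WT pools were male or of both sexes and the FF pools female or of both, and the sex-linked list had 0 gained and 4 lost regions in FF iTreg-IEL and 0 gained and 5 lost in FF exTreg-IEL.

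ThPOK binding was mapped in Treg cells of spleen and lymph node, expanded in mice by an IL-2 complex. The main list held 37368 regions, of which 61.2% lay in genes, and 38.3% to 40.6% overlapped a region of an ATAC list. This share was 15.6% to 18.7% with reciprocal overlap, and 59.8% to 63.0% for the other deposited list. The strongest lay at Eif3e, a subunit of a translation initiation factor (chromosome 15, 43282543 to 43282916), followed by Lars2, Usp31, Aftph and the pair Snx1 and Ciao2a, and all 5 overlapped every ATAC list. Zbtb7b itself had 8 regions within 10 kb, Foxp3 6, Ikzf2 6, Runx3 5, Gzmb 3, Cd8a 1 and Gzma 0. In this order these counts were 2, 2, 1, 2, 1, 0 and 0 at -log10 q of at least 2, and 12, 7, 6, 4, 1, 0 and 0 in the other deposited list of the same precipitation. Of the genes of the natural killer receptor list 4 of 21 had a ThPOK region, below all matched lists (median 16), and of the cytotoxic list 8 of 18 (percentile 0.005), against 15 of 16 of the lymphoid homing list (percentile 90.1) and 21 of 25 of the Treg list (percentile 11.8). In the other list 7 of 21 genes of the natural killer receptor list (below all matched lists), 13 of 18 of the cytotoxic list (percentile 4.05), 15 of 16 of the lymphoid homing list (percentile 93.3) and 21 of 25 of the Treg list (percentile 4.5) had a region. Few genes with a region were also found in the gut residency list (14 of 19, percentile 1.19; 12 of 19, percentile 0.005, in the other list), the Th17 and Th1 effector list (11 of 16, percentile 3.04; 8 of 16, percentile 0.005), the sex-linked list (0 of 4, percentile 0.98; 0 of 4, percentile 0.865) and the epithelial list (7 of 18, percentile 2.88; 4 of 18, percentile 0.035), and in the main list alone in the myeloid list (4 of 16, percentile 0.345; 6 of 16, percentile 14.7), so the shortage was not particular to natural killer and cytotoxic genes. Regions that changed were seldom bound: 2.67% (2.33 to 3.06) of those gained and 4.93% (4.43 to 5.46) of those lost in CD4-IEL against iTreg-IEL, compared with 8.53% and 7.29% of kept regions of like strength. In FF iTreg-IEL 3.83% of gained and 3.90% of lost regions were bound, against 7.55% and 7.33%. In the other list these shares were 2.55% and 6.07% against 11.2% and 9.15% in CD4-IEL, and 4.77% and 4.07% against 9.73% and 9.38% in FF iTreg-IEL. At -log10 q of at least 2 they were 0.318% and 1.03% against 3.18% and 2.80%, and 0.436% and 1.02% against 2.90% and 2.497%. With reciprocal overlap they were 4.97% and 6.61% against 8.97% and 8.13% in CD4-IEL, while in FF iTreg-IEL gained regions were bound in 8.22% against 7.91% of kept ones and lost regions in 6.98% against 8.01%, so the shortage in gained regions of FF iTreg-IEL depended on the overlap rule. The other list held 26956 regions, and 45.0% of the main list overlapped it. Binding was mapped in Treg cells of other tissues, while gained regions were by definition not listed in WT iTreg-IEL. Low binding of gained regions, or of natural killer genes, may thus follow from the cells used. These shares do not bear on ThPOK binding in CD4-IEL. Neighbouring genes of the natural killer receptor list can also lack a region together, which the matched lists do not reflect.

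Single cells addressed which states each tissue holds. In the MLN, 78.6% (76.5 to 80.6) of cells were naive or central-memory-like, against 2.56% in the LPL and 3.49% in the IEL library. CD8αα-IEL-like cells made up 35.9% (34.2 to 37.7) of the IEL library and 0.360% of the LPL library. With at least 200 genes and under 20% mitochondrial UMIs the IEL share was 23.4%. Treg-like cells made up 19.8% (18.3 to 21.4) of LPL and 21.7% (20.2 to 23.2) of IEL, and 0.329% of MLN. Nearly all cells of the Treg-like clusters came from the gut, so Treg cells of MLN may lie in clusters named otherwise. Of 239 MLN cells with a tdTomato UMI, 2 were Treg-like, 124 naive-like and 110 unnamed. The MLN share thus does not measure how many Treg cells that library held. Th1-like (15.6%) and Th17-like (15.1%) cells were found in LPL alone, and clusters that hold 1 library may be that library. Both names depended on the clustering, with 31.3% Th1-like and 0% Th17-like cells without Scrublet doublets and 0% of either at resolution 0.5. Between 20.5% and 42.8% of each library stayed unnamed, a share that also depended on the processing. With the looser cell filter it was 35.5% in MLN and 48.8% in LPL. The gate is stated only as sorted lymphocytes. Cells with a tdTomato UMI in the IEL library were Treg-like in 49.7% (46.5 to 52.9) and CD8αα-IEL-like in 17.3% (15.0 to 19.8), and cells without one in 7.61% and 45.3%.

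Treg-like cells of the gut carried Gzma RNA beside the markers that named them. Of those in LPL, 476 of 495 were of a cluster with no IEL cell, and 633 of those in IEL were of another that held 19 LPL cells, so differences between the tissues within this class are between clusters. Ikzf2, a marker of the class, was at 2919 CPM (2819 to 3022) in Treg-like cells of LPL and at 1249 (1192 to 1307) in those of IEL. Gzma, which encodes granzyme A, was at 10419 CPM in Treg-like cells of LPL, 15246 in those of IEL and 31764 in CD8αα-IEL-like cells, for which it is a marker. It had a UMI in 90.0% of IEL Treg-like cells (86.0% after thinning; median depth 2137 UMIs), against 36.3% (26.7%; median depth 2227) of naive-like cells of the same library, which should lack it. In LPL these shares were 80.0% (77.7% after thinning; median depth 1987) and 15.6% (4.69%; median depth 2006.5). Cd8a had a UMI in 3.32% (2.07 to 5.03) of IEL Treg-like cells and 2.94% (0.611 to 8.36) of naive-like cells, so it was at background in the former (2.30% and 0.990% after thinning). Levels of tdTomato were 880 CPM (825 to 937) and 894 (846 to 943) in Treg-like cells of LPL and IEL and 96.7 (85.4 to 109) in CD8αα-IEL-like cells, near the 105 (68.4 to 153) of naive-like IEL cells. The GFP reporter was at 2021 CPM in Th17-like, 1746 in Th1-like and 1383 in CD8αα-IEL-like cells, and at 412 and 194 in Treg-like cells of LPL and IEL.

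**Figure D5:**
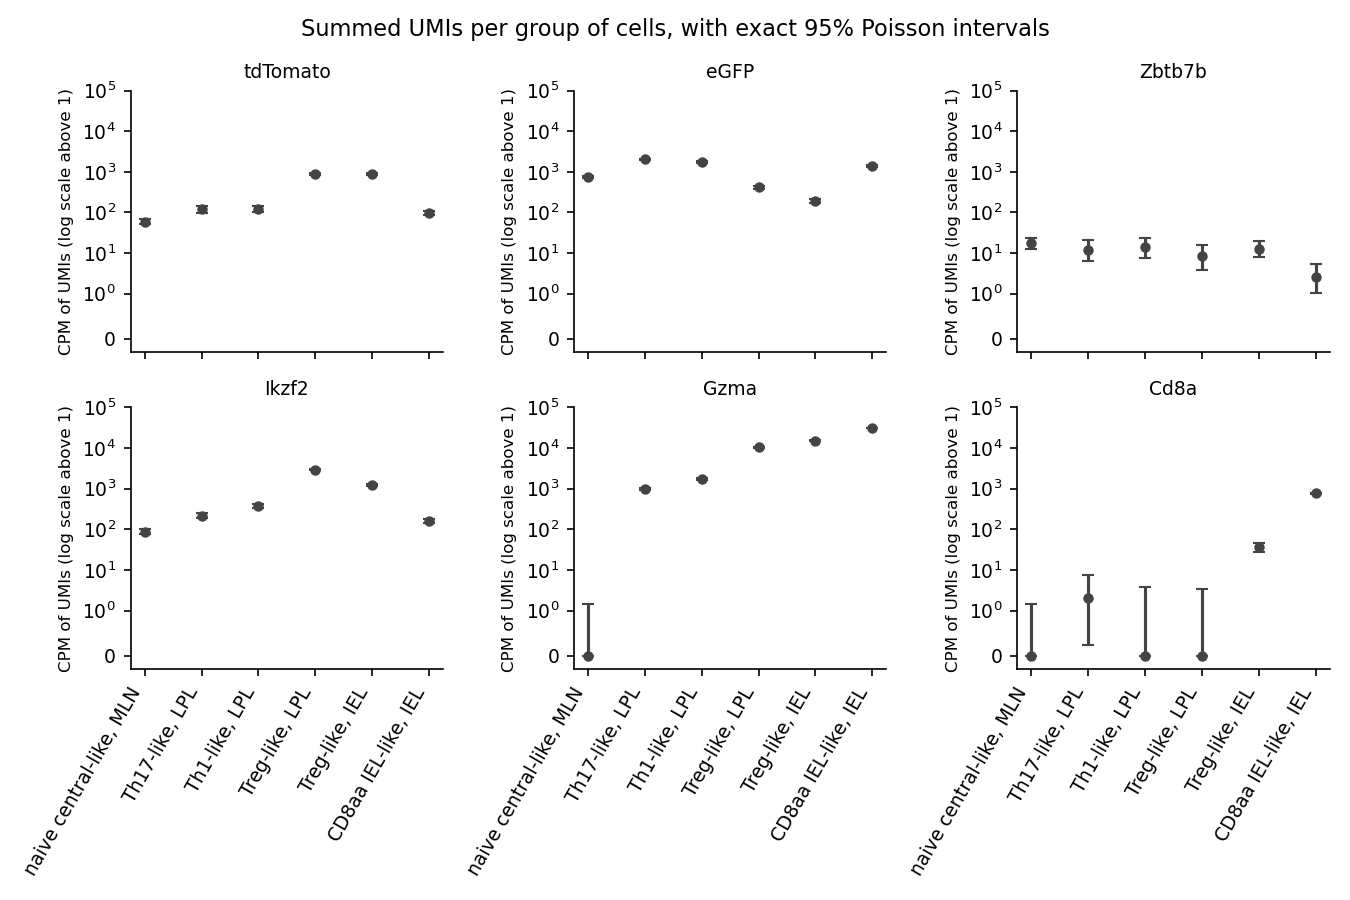
Levels (CPM of UMIs, log scale above 1) of 6 features in groups of single cells, with exact 95% Poisson intervals for counting error. In Treg-like cells of IEL, tdTomato was at 894 CPM, eGFP at 194 and Gzma at 15246.

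Across whole libraries, some lists differed between the tissues. Lymphoid homing genes were lower in the gut than in MLN, with 16 of 16 lower in IEL (median log2 ratio -3.31). Cytotoxic genes were higher in IEL than MLN in 17 of 18 (3.75) and gut residency genes in 15 of 18 (3.30), among them Itgae at 254 and 15.1 CPM. Lists of other cell types and of dividing cells differed there too, with cell cycle genes higher in 16 of 16 (1.79), epithelial markers higher in 8 of 15 (1.36) and B cell markers lower in 6 of 12 (-0.99). Between IEL and LPL, 10 of 18 cytotoxic genes were higher in IEL and 5 lower (0.50), with Gzma at 17737 and 3605 CPM. Markers of γδ and innate T cells moved the same way, with 4 of 8 higher and 1 lower in IEL than LPL (0.78) and 5 of 7 higher and 2 lower in IEL than MLN (3.83), and Tcrg-C2 had a UMI in 83.3% of CD8αα-IEL-like (64.2% after thinning), 43.3% of Treg-like (29.6%) and 2.94% of naive-like cells (0.990%) of the IEL library. Effector genes of Th17 and Th1 cells were lower in IEL in 14 of 16 (-2.22), with Il17a at 32.0 and 358 CPM and Ifng at 37.5 and 205, and Treg genes in 16 of 25 (-0.92), with Il10 at 5.10 and 187 and Areg at 4.84 and 355. Genes of stress and tissue dissociation were also lower in IEL than LPL, in 13 of 16 (-1.76), and T cell receptor response genes in 13 of 19 (-0.72), while 9 of 15 epithelial markers were higher (1.36). Myeloid markers (4 of 8 lower and 1 higher, -1.57) and lymphoid homing genes (11 of 16 lower and 2 higher, -0.73) fell there too. Counts higher and lower are of genes whose intervals did not overlap, and each list above lay outside 95% of matched lists. Inside lay, in IEL against LPL, gut residency genes (8 of 18 higher and 7 lower, 0.04, percentile 63.6), natural killer receptor genes (percentile 26.2) and CD8 lineage genes (percentile 34.0), and in IEL against MLN Treg genes (9 of 25 higher and 6 lower, percentile 66.3). Against MLN, natural killer receptor genes (12 of 14 higher, 2.05) and CD8 lineage genes (10 of 13 higher, 2.19) were at percentile 100 in IEL. Stress genes lay inside in IEL against MLN (6 of 13 higher and 4 lower, percentile 48.0). In LPL against MLN, stress genes (13 of 16 higher, 1.86) and cytotoxic genes (15 of 18 higher, 3.99) were at percentile 100. Outside the lists as matched by symbol, Slc16a11 (24.3-fold), Scin (21.1-fold) and Cd244 (16.0-fold), a receptor of natural killer cells, were higher in IEL than LPL. Cd244 is in the natural killer receptor list under the symbol Cd244a and was missed there, so the percentile of 26.2 lacks it. Cdkn1a, an inhibitor of cyclin-dependent kinases, Ccl20 and Maff were 86.7-fold, 63.7-fold and 59.8-fold higher in LPL.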

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

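The tests of sequencing batch, depth, free RNA and abundant transcripts of admixed cells, the permutation over mice and the score itself were chosen after the results were seen, and the bound on the fall under admixed cells was set before.

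FF exTreg-IEL, the only group of at least 4 libraries, was looked at for a library far from the others in 24 sets of values, and 1 stood out. The scaling factor of exTreg-IEL FF replicate 2 was 0.690, against 0.943 to 0.976 in the other libraries of its group, a gap of 0.886 of the group's range (critical value 0.829). Chance marks about 1 in 20 groups. This library also had the fewest detected transcripts (34813).

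The effect of genotype differed between exTreg-IEL and iTreg-IEL for 3 transcripts by the edgeR interaction test. For ENSMUST00000205054.1 the fitted difference was -10.63 on the log2 scale (adjusted p = 0.00151), for ENSMUST00000092498.11 it was -12.25 (adjusted p = 0.01), and for ENSMUST00000147175.1 it was 8.14 (adjusted p = 0.0283). ENSMUST00000092498.11 was at 0 CPM in all 4 FF exTreg-IEL libraries and 29.4 in FF iTreg-IEL, and ENSMUST00000147175.1 was at 0.0633 CPM in WT and 19.3 in FF exTreg-IEL. Fitted differences that involve a group at 0 depend on the prior count and give no bound. With mouse as a replicate block, edgeR called 0 of these differences, where 4264 had an unadjusted p under 0.05 without it and DESeq2 called 1440.

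The score of the CD4-IEL program also moved differently. FF minus WT in iTreg-IEL exceeded that in exTreg-IEL by 3.37 on the transcripts called between CD4-IEL and iTreg-IEL and by 3.67 on those called between CD4-IEL and iTreg-MLN (exact permutation of genotype over mice, p = 0.0286 for each, the smallest possible, adjusted 0.0571), so neither passed after adjustment. The first list was called with the same WT iTreg-IEL libraries, which can widen the shift in iTreg-IEL. Its 3.37 is thus not an independent test. All 3 FF iTreg-IEL libraries lay above all 3 WT libraries, and above a WT iTreg-IEL library left out of calling the list (3 of 3 times; FF mean minus that single library, 3.49 on average). Without the male mouse, both remaining FF libraries lay above all WT ones (mean difference 2.78).

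For this shift of FF iTreg-IEL, sequencing batch and genotype cannot be told apart, since all FF iTreg-IEL libraries came from 1 batch without WT libraries. On the first list the shift in iTreg-IEL exceeded that in iTreg-MLN, from the same batches, by 2.80 (exact permutation over mice, p = 0.0571), which leaves batch open. Calling that list with the WT iTreg-IEL libraries can widen this difference too. A share of exTreg-IEL or CD4-IEL cells in the FF iTreg-IEL sort may also raise the score. This was examined on the list called between CD4-IEL and iTreg-MLN, whose higher transcripts would need 33.2% or 23.1% of such cells. Measures of the fall of the lower transcripts disagreed. Their median fall was -1.44 (SD 0.34), against the -0.63 or -0.39 that such shares allow. It went beyond by more than its SD in 3 of 3 libraries, which argues against such cells as the whole cause. Their summed fall was -0.87 (SD 0.21), against -0.74 or -0.61 allowed. It went beyond by more than its SD in 1 of 3, and by -0.13 or -0.26 on average. In FF iTreg-IEL replicate 3 it was -0.64, short of the -0.88 or -0.74 allowed. Of 36 higher transcripts at least 100 CPM above WT iTreg-IEL in FF exTreg-IEL, 3 gave under 0.333 of the library's median share in each FF library, among them ENSMUST00000205054.1 at 11.4 CPM where 33.2% of such cells needs 230. Without a map to genes it is not known whether these 3 belong to the same gene or to a marker of the sort. They thus do not decide about admixed cells. For ENSMUST00000205054.1 alone, 1.64% of exTreg-IEL cells in the sort gives the whole rise, so its rise leaves admixed cells open. An effect of ThPOK deletion stays open beside batch and admixed cells.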

How the results depend on the processing

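The design and alternatives were fixed before the data were examined, except the stricter ThPOK list, leaving out both weak exTreg-IEL FF libraries, the scores with their permutation over mice, limma voom without the block, and the DESeq2 splits, which were chosen after seeing the data. Not run, for want of a map from transcripts to genes, were the gene list tests in bulk RNA and the joins of RNA with ATAC gains or ThPOK-bound genes. For each change below the cause was not tested, unless stated. Chance alone gives an unadjusted p under 0.05 for a share of 0.05 of the transcripts tested, against 4.34% to 6.07% in the WT contrasts.

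Counts of called transcripts were within 1.5 times under size factors of DESeq2 in edgeR and under length-scaled counts, in every contrast. In the order iTreg-IEL against iTreg-MLN, preIEL against iTreg-IEL, CD4-IEL against preIEL, exTreg-IEL against iTreg-IEL, CD4-IEL against exTreg-IEL and CD4-IEL against iTreg-IEL, DESeq2 called 1675, 1554, 1619, 2177, 1720 and 2044, edgeR without the low-count filter 76, 14, 30, 80, 12 and 191, and edgeR with mouse as a replicate block in place of batch 21, 0, 4, 0, 0 and 33 (unadjusted p under 0.05 in the reported fit: 3117, 2386, 2679, 3119, 2406 and 3339). Without the batch term, preIEL against iTreg-IEL had 1 and CD4-IEL against preIEL 22. With 1 library left out the ranges were 24 to 38, 0 to 1, 1 to 11, 0 to 23, 0 to 20 and 45 to 55, and a lone preIEL or exTreg-IEL library was assumed to vary like the other groups. The libraries that moved a count by over 1.5 times were CD4-IEL replicates 1, 2 and 3 (1, 1 and 2 against preIEL; 0, 0 and 1 against exTreg-IEL; 52, 49 and 50 against iTreg-IEL), preIEL replicate 1 (1 against iTreg-IEL) and replicate 2 (3 against CD4-IEL), exTreg-IEL replicate 1 (23 against iTreg-IEL, 20 against CD4-IEL), and iTreg-IEL replicates 1, 2 and 3 (1, 0 and 0 against exTreg-IEL; 55, 45 and 45 against CD4-IEL). Without iTreg-IEL replicate 1, iTreg-IEL against iTreg-MLN had 24 and against preIEL 1, and without replicate 3 the former had 25.

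For FF against WT in exTreg-IEL, iTreg-IEL and iTreg-MLN, DESeq2 called 1808, 1072 and 1228, edgeR with sequencing batch as a term 3, 3 and 2 (batch was estimated through 1 exTreg-IEL FF library), limma voom 124, 87 and 96, and limma voom with mouse as a random replicate block 124, 87 and 104 (within-mouse correlation 0.0039), so most of the rise came with the tool. In iTreg-MLN, 12 were called without the filter and 14 without the male FF mouse. Without both weak exTreg-IEL FF libraries, exTreg-IEL had 8. With 1 library left out the ranges were 4 to 8, 4 to 6 and 5 to 6, and exTreg-IEL had 8 without FF replicate 1 or 4. For FF exTreg-IEL against FF iTreg-IEL DESeq2 called 1332, edgeR with mouse as a replicate block 0 (4990 with an unadjusted p under 0.05 without it), and the range was 2 to 6 (exTreg-IEL replicate 2, 4; exTreg-IEL replicate 4, 5; iTreg-IEL replicate 1, 6). For the difference of effects between exTreg-IEL and iTreg-IEL, DESeq2 called 1440, edgeR 5 without the filter, 5 without both weak libraries and 0 with the replicate block (4264 unadjusted without it), with a range of 1 to 6 (1 without WT exTreg-IEL replicate 2 or WT iTreg-IEL replicate 1, 2 or 3; 6 without FF exTreg-IEL replicate 4). For that between iTreg-IEL and iTreg-MLN, DESeq2 called 1061, edgeR 1 without the male mouse, and edgeR 0 in 0 to 0 with 1 library left out (3291 unadjusted).

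Of 20 alternatives for WT calls tested as lists by camera, 14 kept direction and side of the threshold. With an estimated correlation, the list lower in CD4-IEL than preIEL lost its call in iTreg-IEL (adjusted p = 0.332), and the list higher in CD4-IEL than iTreg-IEL lost its call in iTreg-MLN (0.567), as it did with batch as a term (0.642). With batch as a term, the list lower in CD4-IEL than preIEL went higher without a call in exTreg-IEL (0.929), iTreg-IEL (0.927) and iTreg-MLN (0.642), of which the reported fit had called iTreg-IEL alone. The overlaps of genotype calls were the same at an adjusted p of 0.1.

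Of ATAC counts, 38 of 48 alternatives stayed within 1.5 times. With equal list sizes, preIEL against iTreg-IEL gained 6063, CD4-IEL against preIEL lost 8979, FF iTreg-IEL gained 4458, FF exTreg-IEL lost 7174 against WT, and FF exTreg-IEL against FF iTreg-IEL gained 5926 and lost 6951. With reciprocal 50% overlap, preIEL lost 9291, FF iTreg-IEL gained 10967, FF exTreg-IEL gained 8725 against WT and 7410 against FF iTreg-IEL. Shares of regions gained in CD4-IEL became, with equal list sizes, 49.4% in exTreg-IEL, 17.4% in preIEL, 36.1% in FF exTreg-IEL and 18.0% in FF iTreg-IEL, with reciprocal overlap 26.0% and 26.1% in the last pair, and with -log10 q of at least 5 20.3% in FF exTreg-IEL. Shares of lost regions became, with equal list sizes, 45.7% in exTreg-IEL, 51.7% in FF exTreg-IEL and 67.1% in FF iTreg-IEL, with reciprocal overlap 42.6%, 35.2% and 58.3% in these and 56.2% in preIEL, and with the stricter q 42.5% in exTreg-IEL, 71.9% in preIEL and 66.4% in FF iTreg-IEL. Within 50 kb, 5 of the 16 loci had fewer regions in CD4-IEL. Of 192 alternatives for region counts at single loci, 114 stayed within 1.5 times, and of 512 for list percentiles, 439 stayed below, above or inside the middle 95%. Against iTreg-IEL, gut residency in CD4-IEL went to 91.5 (equal sizes) and 94.0 (stricter q), CD4 helper in CD4-IEL to 3.25 (50 kb), and the CD8 lineage list in preIEL to 2.91 (stricter q) and 3.88 (reciprocal overlap) and in exTreg-IEL to 91.2 (equal sizes). Lymphoid homing in CD4-IEL against preIEL went to 3.32 (equal sizes). In FF against WT iTreg-IEL the Treg list went to 99.5 (equal sizes) and 99.9 (50 kb), natural killer receptors to 1.77 (stricter q) and 1.64 (reciprocal overlap), and epithelial markers to 24.4 (equal sizes) and 8.1 (stricter q), and in exTreg-IEL the last went to 3.12 (equal sizes).

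The ThPOK list held 8564 regions at -log10 q of at least 2. The share with an ATAC region was 61.4%, 61.0%, 61.9%, 63.0%, 59.8% and 62.2% for the other deposited list (exTreg-IEL, CD4-IEL, iTreg-IEL, preIEL, FF exTreg-IEL, FF iTreg-IEL), and 15.6%, 15.6%, 16.0%, 16.4%, 18.7% and 18.2% with reciprocal overlap. Of 16 alternatives for the bound share of changed regions, 3 stayed within counting error, and gained regions of FF iTreg-IEL were bound in 3.83% (main) and 8.22% (reciprocal overlap), below and above the kept ones. Of 32 alternatives for lists of genes with a ThPOK region, 22 kept their place.

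Among single-cell shares, 58 of 84 alternatives stayed within counting error. With 200 genes and 20% mitochondrial UMIs, MLN held 63.7% naive-like, 35.5% unnamed, 0.122% cycling-like and 0% CD8αα-IEL-like cells, LPL 11.9% Th17-like and 48.8% unnamed, and IEL 23.4% CD8αα-IEL-like and 46.8% unnamed. At resolution 0.5, MLN held 84.1% naive-like and 14.7% unnamed, LPL 21.6% Treg-like, 2.56% cycling-like, 72.3% unnamed and 0% Th1-like or Th17-like, and IEL 42.9% CD8αα-IEL-like and 27.1% unnamed. At 1.2, MLN held 63.4% naive-like, 35.8% unnamed and 0% CD8αα-IEL-like, and IEL 33.6% CD8αα-IEL-like and 37.1% unnamed. Without Scrublet doublets, MLN held 18.4% unnamed and 0% CD8αα-IEL-like, and LPL 31.3% Th1-like and 0% Th17-like. Th1-like and Th17-like shares thus depend on the clustering. With all barcodes, 47 of 48 list ratios between tissues kept their place among matched lists (below, above or inside the middle 95%), and epithelial markers in LPL over MLN went from 1.61 (percentile 97.3) to 1.69 (98.4). Myeloid markers in IEL over LPL went from -1.57 to -0.90, and B cell markers in LPL over MLN from 0.13 to -0.04. Detection in bulk RNA was limited, even in the better expressed transcripts that the simulation changed. Of simulated changes of 2 on the log2 scale, 10% and 2% were called in the WT and genotype fits.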

Other observations

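The tests of depth, free RNA and other splits of the samples, and the separation of Ikzf2 from its list, were chosen after the results were seen.

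Of 62 regions near the Treg list lost in CD4-IEL against iTreg-IEL, 56.5% (43.3 to 69.0) were found in exTreg-IEL, against 44.5% (43.1 to 45.9) of lost regions of the same fold elsewhere. Cells of iTreg-IEL in the exTreg-IEL sort may give such regions, but would give them near all genes alike. The intervals overlap, and without Ikzf2 the share was 42.9% (26.3 to 60.6) against 45.9%, so the test leaves such cells open. At Ikzf2 alone it was 74.1% (53.7 to 88.9), against 41.8% (40.1 to 43.5). A slower loss of Ikzf2 regions is a hypothesis that 1 pooled list per group leaves untested.

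The GFP reporter of ThPOK was lower in Treg-like cells than in the other cells of the same library, at 194 CPM (172 to 218) against 1231 (1203 to 1259) in IEL and 412 (374 to 452) against 1665 (1630 to 1701) in LPL. Depth of the cells would leave this ratio at 1, and it was 0.157 in IEL and 0.247 in LPL. Free RNA may supply part of the eGFP UMIs: a cluster of 31 cells with B cell and myeloid markers held 907 CPM (705 to 1150), but it also held T cell RNA (Cd3e at 334 CPM), so it sets no background. Zbtb7b itself was at 12.9 CPM (7.78 to 20.2) in Treg-like cells and 7.45 (5.45 to 9.93) in the others of IEL, and at 8.23 (3.76 to 15.6) and 10.7 (8.04 to 14.0) in LPL, with intervals that overlapped in both, so this depth leaves open whether it followed the reporter. No biological explanation was tested.

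Other splits of the same libraries were fitted for groups of at least 3. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real grouping called 48 transcripts for iTreg-IEL against iTreg-MLN (highest other 0), 116 for CD4-IEL against iTreg-IEL (highest other 0), 5 for iTreg-IEL FF against WT (highest other 0) and 6 for iTreg-MLN FF against WT (highest other 2), so 1 of 10 splits, the real one, called as many in each. For the difference of genotype effects between iTreg-IEL and iTreg-MLN edgeR called 0 in the real grouping, the highest other was 1, and 10 of 10 called as many. There 3291 (5.50%) had an unadjusted p under 0.05, near the share that chance gives, and DESeq2 called 1061. For FF exTreg-IEL against FF iTreg-IEL the real grouping called 2, 5 of 35 splits called as many and the highest called 11, so chance was not excluded. The libraries of 3 mice were on both sides there. Of the 8 splits that part these mice as the real one does, 1, the real one, called 2 and the highest other called 1, too few splits for a share under 0.05. The split with 11 set both libraries of mouse 6 against both of mouse 7, so it also set these mice against each other, and with mouse as a replicate block edgeR called 0. By DESeq2, the 9 other splits of CD4-IEL and iTreg-IEL called 900 to 1310 transcripts, against 2044 in the real grouping.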
